A study of Mus musculus with 4 samples.

How the data were processed

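The study sequenced polyadenylated RNA from 4 libraries of mouse bone marrow-derived macrophages, 1 library for each combination of 2 genotypes and 2 pressure conditions. Macrophages were grown from marrow with M-CSF, a growth factor of the macrophage lineage, at 50 ng/mL, and spent 6 h in a pressure chamber, per the labels' protocols. Libraries were made with an Illumina TruSeq mRNA kit and sequenced as paired reads of 75 bases, per the same protocols. Whether the kit marked the strand of the RNA is not given in the sources used here. The submitters' processing notes list CASAVA 1.8, FastQC, TopHat2, Bowtie2 and Cufflinks, and the genome builds GRCm38 and mm10. The notes give no role or order for these names.

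The deposited file analysed here is a gene annotation in GTF format that serves the whole series. It holds 1500259 lines of features with their coordinates, which are 1-based starts and ends on GRCm38. Its score column holds only a dot on each of those lines, and 0 of its columns hold a value of a library. Its gene and transcript identifiers are Ensembl ones, and its attributes include the start-site and protein groups that Cufflinks uses. The file has no header line, and its release number is not given in the sources used here. Expression values of the 4 libraries were not analysed here, so the depth of each library is unknown, and no difference in expression, error or p-value is given. The series has 1 library per group, so any difference between those libraries would have no replicate check.

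Coordinates were read from the exon and coding-sequence lines with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1. The union exon length of a gene is the number of bases covered by the exons of any of its transcripts. An exon overlap is the part of that union which exons of another gene also cover, on the same or on the opposite strand. An overlap of at least 1 base counted, and at least 100 bases was the alternative. The design, the alternatives, 13 gene lists with 142 symbols and the rule for named genes were fixed before the data were examined. Because the file might have held either kind of content, the plan covered expression values and an annotation, and only the second part could be run. The rule names Piezo1 and Piezo2 and, in each list, the members with the longest and the shortest union exon length and the member with the largest overlapped share. Not every gene that this rule takes is named in the text. Every other gene named below was chosen after its values were seen.

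The median union exon length of each list was set against the medians of 10000 random lists of the same size, drawn from the 22159 protein-coding genes. This percentile describes the annotation and is not a test across samples. A list was said to stand apart when it lay below the 2.5th or above the 97.5th percentile. Of 13 lists, 0.65 would do so by chance. Alternatives for the lists took the longest transcript of each gene in place of the union, or drew the random lists from all genes. For the length of Piezo1 and its overlap, the protein-coding transcripts alone were also used. A share of genes was said to have moved when an alternative fell outside its exact 95% binomial interval.

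GENCODE M21, an annotation of the same build, was used for comparison after the deposited file had been seen. Of the deposited gene identifiers, 45229 (98.2%) also occur in GENCODE M21, and 45212 of these lie on the same chromosome and strand in both. The transcript sequences of GENCODE M21 were searched for windows of 75 bases, the read length, that a listed gene shares with another gene on either strand. The functions were tested on simulated data. All 400 simulated genes had the right union length and the right overlapped bases, and the shared windows of 30 simulated genes were recovered. Of 200 unchanged lists of 10 simulated genes, 9 (4.5%) fell outside the middle 95%. Of 200 lists of 10 genes made 4 times shorter, 189 (94.5%) fell below the 2.5th percentile. Smaller shifts and other list sizes were not simulated, so this rate does not apply to them.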

Results

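The study asked how macrophages respond to rhythmic mechanical force, and whether that response needs PIEZO1, an ion channel of the plasma membrane that opens when the membrane is stretched. Bone marrow-derived macrophages came from mice with floxed Piezo1 alleles. They came either without Cre (called WT in the labels) or with LysM-Cre, which removes floxed sequence in myeloid cells (called KO). Cells of each genotype were kept for 6 h under static pressure or under a cyclic hydrostatic pressure with an amplitude of about 15 mmHg, made by opening an intake valve for 0.6 s and an exhaust valve for 0.4 s in turn. This gave 4 groups of 1 library each. The design implies a comparison of cyclic with static pressure in each genotype, a comparison of the genotypes under each pressure, and the difference between the responses of the 2 genotypes. Expression values for these comparisons were not analysed here, and the depth of the libraries is unknown. The results below describe the gene models of the deposited annotation, for the targeted gene and for the genes those comparisons would address.

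The annotation held 46078 genes with 110379 transcripts and 690647 exon lines. Protein-coding genes made up 22159 of these genes (48.1%), followed by 5954 processed pseudogenes (12.9%) and 3413 long intergenic noncoding RNAs (7.4%). Next came 2250 miRNA genes (4.9%), 2164 unprocessed pseudogenes (4.7%) and 2068 genes classed as antisense (4.5%). Chromosomes 1 to 19, X, Y and MT held 45706 genes, and patches and unplaced sequences held the remaining 372. The median protein-coding gene had 2 transcripts and a union exon length of 2905 bases, and 8641 protein-coding genes had a single transcript. Exons of 7104 genes (15.4%) overlapped exons of a gene on the opposite strand by at least 1 base. Among protein-coding genes this held for 4373 (19.7%). Overlaps with another gene on the same strand were less frequent, at 2621 genes (5.7%).

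Piezo1 (ENSMUSG00000014444) was annotated on the minus strand of chromosome 8 from 122481698 to 122551329, a span of 69632 bases. Its 9 transcripts comprised 2 protein-coding ones, 2 classed as nonsense-mediated decay and 5 with retained introns, and their exons covered 9933 bases. The longest coding transcript, Piezo1-201, had 51 exons that summed to 8216 bases, with 7638 coding bases before the stop codon. Its exons were short, with a median of 149 bases and a range from 43 bases in exon 4 to 534 bases in exon 51. Intron 1 spanned 37165 bases, against a median of 138 bases over the introns of this transcript. The second protein-coding transcript, Piezo1-003, began downstream of exons 1 to 11 and had 40 exons and 6598 bases. Taking the union of all transcripts in place of Piezo1-201 made the gene 1.21 times longer, so a length-normalised value of Piezo1 depends on the gene model. The paralogue Piezo2 (ENSMUSG00000041482) on chromosome 18, from 63010213 to 63387183, was the longest of the listed channels at 14566 exon bases, and 0 of them overlapped exons of another gene.

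The 3′ end of Piezo1 lay over the 3′ end of Ctu2 (ENSMUSG00000049482), which encodes a cytosolic enzyme subunit that adds sulphur to tRNA. Ctu2 was annotated on the plus strand from 122476143 to 122484138, so the genes converge. Exons of both genes covered the 2441 bases from 122481698 to 122484138, which is 24.6% of the Piezo1 union and 47.3% of the Ctu2 union. Of the 22159 protein-coding genes, 700 (3.2%) had a share on the opposite strand at least this large. In Piezo1-201 the overlap took in exons 45 to 51, with 1409 of its 8216 bases (17.1%) and 1122 of its coding bases. None of the coding bases of Ctu2 (0 bases) lay within Piezo1 exons, so the Ctu2 side of the overlap is noncoding. The longest protein-coding Ctu2 transcript, Ctu2-001, ended at 122483092 and reached only exons 47 to 51 of Piezo1-201. Between protein-coding transcripts the overlap was 990 bases (12.0% of Piezo1-201). The rest of the overlap came from Ctu2-002, a transcript classed as nonsense-mediated decay, and from introns retained in Piezo1 transcripts. Read pairs that lie wholly within 1 exon of each gene here cannot be assigned to Piezo1 or Ctu2 without strand, whereas pairs with a read across Piezo1 exon junctions can.

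**Figure D1:**
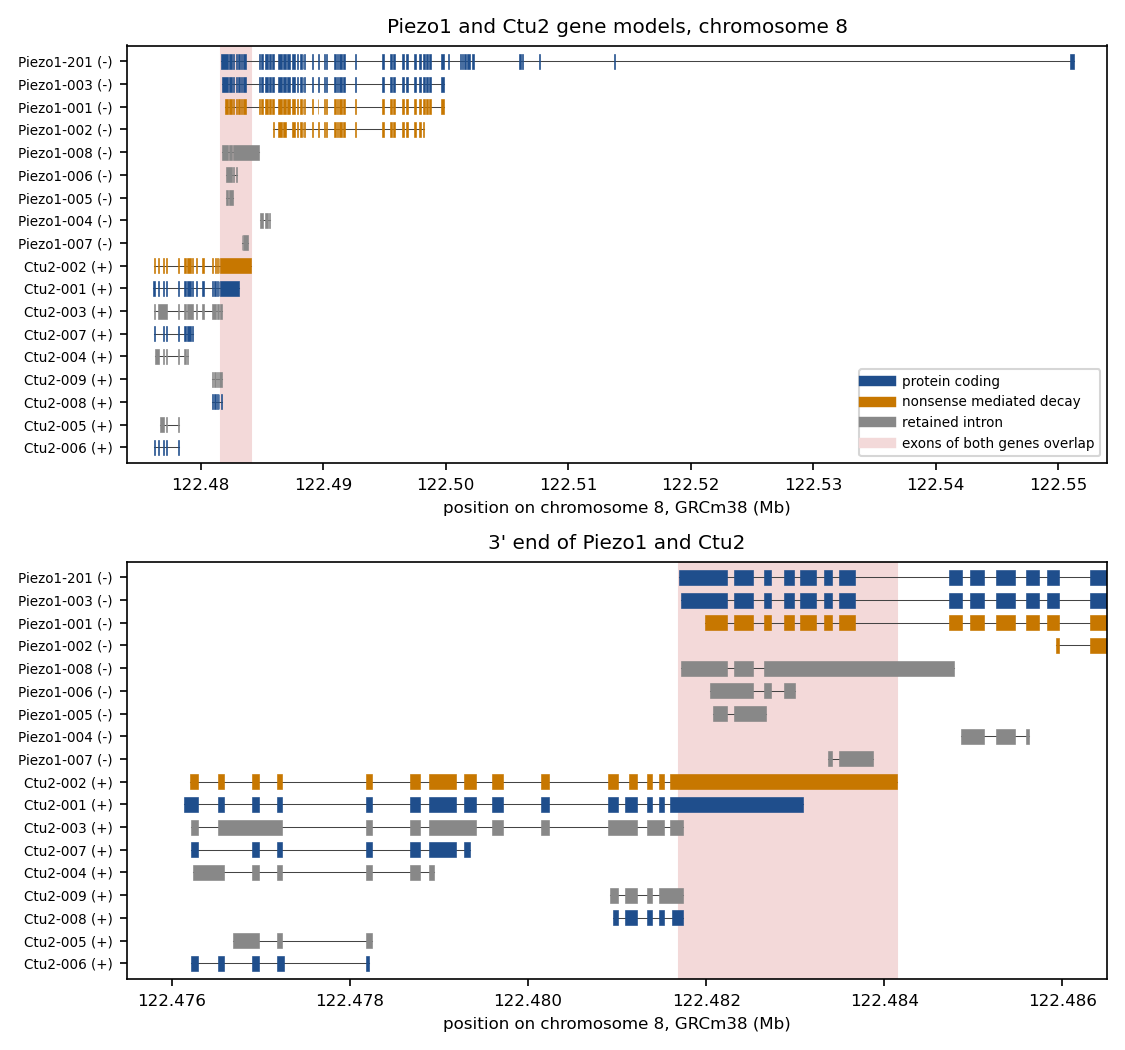
Transcripts of Piezo1 (minus strand) and Ctu2 (plus strand) in the deposited annotation, with position on chromosome 8 (GRCm38, Mb) on the horizontal axis and 1 row per transcript; boxes are exons, coloured by transcript class, and thin lines are introns. The upper panel shows both genes and the lower panel their 3′ ends, where the shaded 2441 bases are covered by exons of both genes and include exons 45 to 51 of Piezo1-201.

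The 13 lists held 142 symbols, 141 of them different, since Itgam stands in 2 lists, and 139 different genes were found. The symbols Ccn1 and Ccn2 had no gene of that name. The annotation carries these genes of YAP signalling under their older names Cyr61 and Ctgf, which the list also held. A single transcript was annotated for 48 of the 139 genes. The median union exon length of 10 of the 13 lists lay within the middle 95% of random lists. The neutrophil markers and the inflammatory cytokines and chemokines were shorter than that range, and the fibroblast and endothelial markers were longer.

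The 20 inflammatory genes had a median of 1757 exon bases (2.1th percentile), with 9 of them on a single transcript. The chemokine gene Ccl4 was the shortest at 660 bases, and Ptgs2, which encodes the inducible cyclooxygenase, was the longest at 4580 bases. Tnf had 1639, Il1b 1907 and Il6 2428 bases. The percentile rose to 78.1 when the random lists were drawn from all genes, noncoding ones included, so the call holds only against protein-coding genes. The 18 hypoxia genes had a median of 3244 bases (67.3th percentile). Their list was made of targets of the transcription factor HIF1A and other hypoxia genes, among them Hif1a itself. The 18 genes ranged from Ankrd37 with 1403 bases to Pdk1, a kinase that restrains pyruvate dehydrogenase, with 7779 bases. The 16 AP-1 and immediate early genes had a median of 2585.5 bases (31.3th percentile), from Ier3 with 1131 to the AP-1 subunit gene Fosl2 with 9680 bases, and 9 of them had a single transcript. In the endothelin pathway of 6 genes the median was 4075 bases (79.8th percentile). Edn2 was the shortest at 1462 bases, the receptor gene Ednra the longest at 5476, and Edn1, the gene of endothelin 1, had 2344 bases on a single transcript.

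The 11 interferon-stimulated genes had a median of 3020 bases (54.2th percentile), with Isg15, which encodes a ubiquitin-like modifier, the shortest of them at 756 bases. The 11 mechanosensitive channels had a median of 4943 bases (96.2th percentile), and the potassium channel gene Kcnk4 was the shortest of them at 1715 bases. For the 9 YAP/TAZ and adhesion genes found, the median was 4081 bases (84.2th percentile), from Ankrd1 at 1765 to Tln1, which encodes the integrin-binding protein talin, at 9801 bases.

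Among markers of the cell types that a marrow culture can hold, the 11 macrophage markers had a median of 2695 bases (40.4th percentile). These ran from Cd68 at 1257 bases to the integrin gene Itgam at 6377 bases. The 9 neutrophil markers had the lowest median, 942 bases (0.2th percentile), with S100a9, a calcium-binding protein gene, at 522 bases and the lactoferrin gene Ltf at 3450 bases. This call, too, was lost against all genes, where the list stood at the 31.3th percentile. The 10 lymphocyte markers had a median of 1498.5 bases (2.8th percentile), from Nkg7 at 878 to the B-cell gene Ms4a1 at 6187 bases. In GENCODE M21 the median of this list was 2445 bases (11.6th percentile). The 6 dendritic cell markers had a median of 3918 bases (76.6th percentile), between the chemokine receptor gene Ccr7 at 1978 and Zbtb46 at 8508 bases. The 8 fibroblast and endothelial markers had the highest median, 7796.5 bases (99.8th percentile), between the decorin gene Dcn at 2084 bases and the collagen gene Col1a2 at 12136 bases. The 5 erythroid markers had a median of 1534 bases (11.2th percentile), from the alpha-globin gene Hba-a1 at 812 bases to Alas2, which encodes the first enzyme of haem synthesis in red cells, at 2403 bases.

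**Figure D2:**
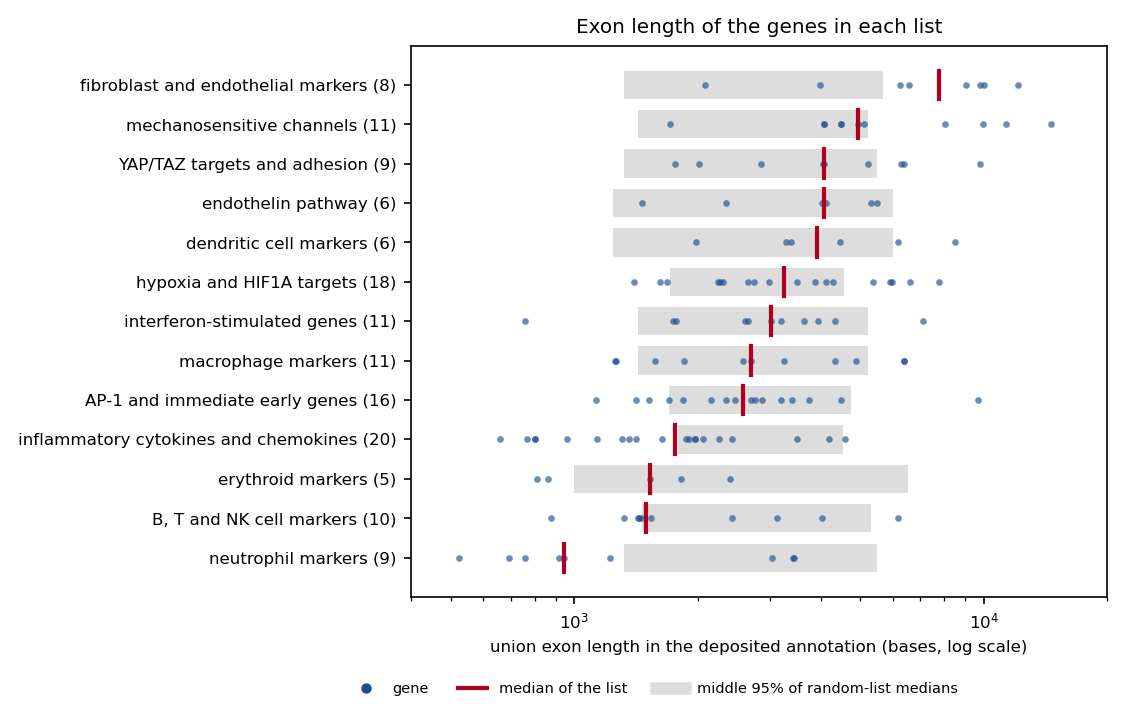
Union exon length (bases, log scale) of each gene in the 13 lists, with the number of genes found in brackets; points are genes, red lines are list medians and grey bars span the middle 95% of medians of 10000 random lists of protein-coding genes. The medians of the neutrophil markers (942 bases) and of the inflammatory genes (1757 bases) fall below their bars, and that of the fibroblast and endothelial markers (7796.5 bases) above its bar.

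Exons of 28 of the 139 listed genes overlapped those of another gene. The other gene lay on the opposite strand for 25 genes (18.0% of the 139, against 19.7% of protein-coding genes) and on the same strand for 4. In the deposited annotation, only 4 genes had over 20% of their union on the opposite strand of another gene's exons, and Piezo1 was 1 of these. This count depends on the release: in GENCODE M21, Fosl1 had 1163 of 2033 bases overlapped in this way and Jund 877 of 1668. The other genes above 20% in the deposited annotation included Vcl, which encodes the adhesion protein vinculin (chromosome 14, 20929433 to 21033673), with 2087 bases (39.9%) over Ap3m1. Ankrd37 (chromosome 8, 45996902 to 45999867) had 406 bases (28.9%) over Lrp2bp and Ufsp2. Ctgf (chromosome 10, 24595442 to 24598683) had 665 bases (23.2%) over Gm15270. In further lists the largest overlapped share was 18.9% in Jund, 17.8% in the M-CSF receptor gene Csf1r, 15.5% in Alas2, 15.0% in the myeloperoxidase gene Mpo, 12.0% in the cytokine gene Csf2, 6.5% in Pdgfra, 5.6% in Clec9a and 1.7% in Ednra. None of the lymphocyte markers (0 of 10) had an overlap. In the inflammatory list 4 of 20 genes had an overlap, which is near the share among protein-coding genes. These were Csf2, Il1a with 222 bases (11.2%), Cxcl10 with 133 bases (5.9%) and Il1b with 25 bases (1.3%).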

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

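The uses of GENCODE M21 and the overlap between protein-coding transcripts were chosen after seeing the data. The length of Piezo1 was 9933 bases as the union of all transcripts, 8216 for the longest transcript, 8217 for the union of protein-coding transcripts and 9935 in GENCODE M21. Its overlap with Ctu2 was 2441 bases in both annotations and 990 between protein-coding transcripts. The number of lists standing apart was 3 with the union, with the longest transcript and in GENCODE M21, with the same call for each of the 13 lists. It was 5 when random lists came from all genes: 4 lists were gained and 2, the neutrophil and inflammatory ones, were lost, with a background that adds noncoding genes. The listed genes with an exon overlap numbered 28, against 23 at a minimum of 100 bases and 38 in GENCODE M21. The share of genes with an opposite-strand overlap was 15.4%, against 12.2% at a minimum of 100 bases, 19.7% for protein-coding genes only and 16.7% in GENCODE M21. The shorter Piezo1 models and overlap follow from leaving out transcripts, and the cause of the shifts in GENCODE M21 was not tested. Of 15 other settings chosen before the data were examined, 8 need expression values and were not run. No leave-one-out or paired analysis applied, because each group has 1 library and no library value was analysed. Depth limits nothing printed here, as no value is a count of reads.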

Other observations

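The tests that use GENCODE M21, shared windows, protein-coding transcripts of Piezo1 and Ctu2, exons 20 to 23 or lists matched on transcript number were chosen after the gene models had been seen. In the transcript sequences of GENCODE M21, 89 of the 139 listed genes shared 0 of their 75-base windows with another gene, while 50 shared at least 1. Among the erythroid markers, Hba-a1 shared 67.9% of its windows with its twin Hba-a2, and the beta-globin gene Hbb-bs shared 51.5% with Hbb-bt. In the hypoxia list, 4 of 18 genes shared over 10% on either strand. Pgk1 shared 52.8% of its windows, nearly all with Pgk1-rs7, the cell-death gene Bnip3 shared 34.4%, the glycolytic gene Eno1 shared 22.6% with Eno1b, and Ankrd37 shared 13.3% with Lrp2bp. Other glycolytic genes of that list shared little, with 2.7% for Ldha, 0.7% for Aldoa and 0.0% for Hk2. Ifit3, an interferon-stimulated gene, shared 41.1% with Ifit3b. Itgam, a common macrophage marker also known as CD11b, shared 65.2% with Gm49368. Of its exon bases, 0 were overlapped in the deposited annotation, against 3450 on the same strand in GENCODE M21. Shared windows were not searched in the deposited annotation. In the inflammatory list, 0 of 20 genes lay above 10%, with a highest share of 7.9% in Il1a, and Cxcl2 and Cxcl3 had 101 windows in common. The endothelin, neutrophil, lymphocyte, dendritic cell, and fibroblast and endothelial lists also had 0 genes above 10%, with highest shares from 0.4% to 6.9%. Lyz2, the gene whose locus carries LysM-Cre, shared 6.0% of its windows with Lyz1. On the opposite strand, 8 genes shared over 10% of their windows, among them Fosl1 with 50.2% (Ccdc85b), Jund with 45.9% (Gm11175), Vcl with 24.9% (Ap3m1) and Piezo1 with 21.9% (Ctu2). Fosl1 and Bnip3 had 0 overlapped bases in the deposited annotation, against 1163 and 504 on the opposite strand in GENCODE M21.

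The labels do not say which Piezo1 exons are flanked by loxP sites. In a widely used floxed allele they are exons 20 to 23, and whether this allele was used is not given in the sources used here. In Piezo1-201 these 4 exons span 122492607 to 122495859 and hold 637 bases, which leaves a remainder of 1 after division by 3, so that their removal would shift the reading frame. They make up 7.8% of Piezo1-201, and 93.6% of the Piezo1 union lies outside them. Of the 9 Piezo1 transcripts, 5 hold none of the 4 exons, and these are the 5 with retained introns. Both protein-coding transcripts hold all 4 exons. Ctu2 exons cover 0 bases of them. A gene-level value for Piezo1 would therefore draw mostly on exons that such a deletion leaves in the genome. Reads over exons 20 to 23 would be free of Ctu2. Whether such a frame shift changes the level of the whole Piezo1 RNA was not tested.

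Piezo1 and Ctu2 share 2441 exon bases, and 2 explanations for this from the annotation were tested. The first was that only noncoding transcripts overlap, but the protein-coding transcripts of both genes share 990 bases. The second was that the overlap is particular to the deposited annotation, but GENCODE M21 also has 2441 shared bases. The first value argues against the first explanation. The second shows that the overlap is not limited to the deposited annotation. GENCODE M21 is not an independent check, because 80.2% of the gene identifiers in both annotations have the same union exons. How much of the RNA at this site comes from either gene in macrophages stays open, since no reads were analysed. No biological explanation was tested.

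The inflammatory and neutrophil lists had short union exon lengths per gene, and a technical explanation may be that few transcripts are annotated per gene. Against 10000 random protein-coding lists matched on the number of transcripts, the inflammatory list moved from the 2.1th to the 11.8th percentile, inside the middle 95%, where the matched lists had a typical median of 2267.5 bases against 1757. Few annotated transcripts per gene therefore remain a possible explanation for this list, although single-transcript genes may also be short for other reasons. The list's median of 2 transcripts per gene equals that of protein-coding genes, yet matching lowered the typical random median from 2905.5 to 2267.5 bases. The equal medians therefore do not speak against this explanation. Another value goes the other way: by the longest transcript of each gene, which adds up no exons over transcripts, the list still stood at the 1.6th percentile. The neutrophil list stayed at the 0.1th percentile, with 942 bases against a typical matched median of 2596. Its genes had a median of 2 transcripts, equal to that of protein-coding genes, and 3 of 9 had a single one. The matching could therefore change little, and its result adds little to the finding that this list was not short of transcripts. No biological explanation was tested.

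Gene models of the listed genes differ between releases. Of 139 listed genes, 91 had the same union exons in GENCODE M21, and 48 had another union length. A change was found in 27 of the 48 genes with a single transcript in the deposited annotation and in 21 of the 91 with 2 or more. In GENCODE M21, 10 genes were at least 1.5 times longer, and 9 of these had a single transcript in the deposited annotation. The immediate early gene Egr3 grew from 1416 to 4406 bases (3.11 times), Cd3e from 1436 to 4080 (2.84 times), Dcn from 2084 to 5838 (2.8 times) and Kcnk4 from 1715 to 4465 (2.6 times). Jund shrank from 2878 to 1668 bases (0.58 times). Among all shared protein-coding genes, 3250 of 21805 (14.9%) were at least 1.5 times longer in GENCODE M21, and 80 were at least 1.5 times shorter. Piezo1 changed by 2 bases.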
